A study of Mus musculus with 24 samples.

How the data were processed

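The data were ChIP-seq libraries of the mouse melanoma line YUMMER1.7, fixed per the labels' protocols in 1% formaldehyde for 10 min. Antibodies against KDM5B, SETDB1, H3K9me3, H3K4me2 and H3K4me3, and an input without antibody, were used in control cells and in cells with a deletion of Kdm5b (KO), giving 24 samples in 12 groups of 2. Groups were taken from the antibody and genotype labels. The control samples carry a control-knockout genotype label, and the KO replicates are labelled deletion 1 and deletion 2. Whether the replicates came from separate cultures is not given in the sources used here.

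For each antibody and genotype the authors deposited 1 list of merged regions, so the 20 antibody samples are represented by 10 lists. The values in each list are the start and end positions of the regions on mm10, per the labels and as deposited by the authors, with no height, fold, p-value or read number beside them. A further list deposited for KDM5B held 95908 regions and was identical to the merge of the control and KO KDM5B lists, so it carried no information of its own. CASAVA, Bowtie2, Subread and featureCounts are named in the submitters' processing notes without their roles or versions. The peak caller, its threshold, and whether the merging joined the regions of both replicates or the reads are not given in the sources used here. No list was used for the 4 input samples. The number of reads behind a list is unknown, so the length of a list depends on sequencing depth and on the threshold as well as on the chromatin.

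Regions were taken as they stood, and positions are printed counting from 1. A region was called found in another list when it overlapped a region there by at least 1 bp. Shares carry Wilson 95% confidence intervals over regions. These cover counting error only, since neighbouring regions are not independent. With 1 pooled list per group there is no spread between replicates, so no test between genotypes was possible and no p-value is given for one. Statements on genotypes compare the lists, and a region or gene is described as listed in control only, in KO only or in both.

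Overlap within a genotype was compared with circular shifts of one list along each chromosome, 1000 per pair of antibodies, and overlap between genotypes with 200 shifts. To ask whether regions of the other antibodies were found again in KO more or less often where control KDM5B regions lay, regions were split into 5 equal classes of width. The difference was averaged over these classes with weights equal to their sizes, with a 95% interval built from Wilson intervals.

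Genes came from a RefSeq gene table of GRCm38, the assembly that mm10 is a release of, with 21887 protein-coding genes placed on chromosomes. The table gave gene starts and ends but no strand or exons. The planned windows of 1 kb either side of transcription start sites were therefore replaced by windows of 1 kb either side of either annotated gene end, and exons, introns and untranslated regions were not told apart. Since the lists held no score, width took its place wherever regions were ranked. A region's location was that of its centre, as gene end, inside a gene or between genes, and 200000 random positions gave the background. The planned measure of repeat content needs a genome sequence and was not analysed here.

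The analysis plan, including the 17 gene lists, the rule for named genes and 41 alternatives, was fixed before the data were examined. The lists covered H3K9 methylation and retroelement silencing machinery, H3K4 methylation writers and erasers, nucleic acid sensing, interferon-stimulated genes, antigen presentation, the melanocyte lineage, neural crest and dedifferentiated melanoma, germline genes, imprinted genes, clustered protocadherins, zinc finger proteins named Zfp, ribosomal protein genes, Hox genes, olfactory receptors, lymphocyte and myeloid markers, keratinocyte, fibroblast and endothelial markers, and the engineered loci. The genes Mx1, Mx2, Kcnq1ot1, Peg13 and Meg3 had no entry among the placed protein-coding genes and were left out. Rigi had no entry under that name, but its gene was kept in the list as Ddx58. H19, not a protein-coding gene, was matched through a synonym to Nckap1, which thus stands in the imprinted list. Each list's count of genes with a region was set against 10000 random lists of the same size, and again against random lists with the same number of genes carrying a control H3K4me3 region. The percentile describes these lists of regions and is not a test. Percentiles of the net count, genes with a region in KO minus genes with one in control, were obtained in the same way.

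Named genes were Kdm5b and the engineered loci. For each antibody they were also the first 10 genes with a gene-end region in control only and the first 10 in KO only, ordered by the width of that region. The 5 widest regions of the control KDM5B, SETDB1 and H3K9me3 lists, and of the stretches where all 3 overlap, were given with their nearest gene. From each gene list up to 4 members that differed between genotypes, in alphabetical order, and up to 2 that did not could be named. Because wide regions reach over several genes, neighbours in these rankings often share a region.

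Overlap counts, shifted ratios, differences within width classes, gene-end windows and percentiles of random gene lists were tested on simulated data first, and correlations over chromosomes and location shares were not. The overlap counts differed from a direct count in 0 regions over 20 simulated pairs of lists. Scattered lists gave a mean ratio of observed to shifted overlap of 1.00. A planted difference of 10 percentage points between regions with and without KDM5B was estimated as 9.95 points within width classes and as 14.1 points without them. The interval held the planted value in 49 of 50 runs. Alternatives included a reciprocal overlap of 50%, the widest 50% of each list, equal list lengths, merging within 1 kb, autosomes only, windows of 2.5 kb and 250 bp, and leaving out regions that overlap a KO KDM5B region. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.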

Results

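Chromatin occupancy was compared between control and Kdm5b-deleted cells of YUMMER1.7, a mouse melanoma line with engineered lesions in Braf, Pten and Cdkn2 and with UV-induced mutations. KDM5B removes methyl groups from H3K4me2 and H3K4me3, marks of active gene starts. SETDB1 deposits H3K9me3, a mark of silenced chromatin and of repressed retroelements, which the series title names as its subject. The data were 10 lists of enriched regions, 1 per antibody and genotype, each made by the authors from 2 replicates. Depth is unknown for every list, no value has a replicate check, and intervals are 95% Wilson intervals that cover counting error only.

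At Kdm5b itself (chromosome 1, 134560178 to 134632878) the control cells had 1 KDM5B region, 540 bp wide, inside the gene at 134624944 to 134625483, and the KO cells had none. H3K4me3 lay over the start of the Kdm5b annotation in both genotypes, 1908 bp wide in control and 1932 bp in KO. SETDB1 was listed at that gene end in both as well, over 1598 and 1305 bp. The position of the deletion is not given in the sources used here, so these lists do not test it at the locus. Braf carried control KDM5B regions of 382 and 1442 bp, and Pten, a lipid phosphatase and tumour suppressor, 1 of 2507 bp, none of them listed in KO. Cdkn2a and Cdkn2b, which encode inhibitors of the cell cycle, had no KDM5B, SETDB1, H3K9me3 or H3K4me2 region. Both had an H3K4me3 region in each genotype. That of Cdkn2a lay at 89277891 to 89280243 on chromosome 4 in control and at 89281021 to 89282529 in KO, so it was at different places. Per the labels Cdkn2 is deleted, and which part of it is missing is not given in the sources used here.

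The KDM5B list was 20.9-fold shorter in KO, with 94785 regions over 247 Mb in control and 4543 regions over 9.07 Mb in KO. The SETDB1 list was 7.14-fold shorter, with 91875 regions in control and 12867 in KO. The H3K4me2 list was 2.12-fold shorter, with 31833 and 15041 regions. H3K9me3 had 33896 and 24624 regions but nearly the same covered length, 94.4 and 92.7 Mb. H3K4me3 had 22040 regions in control and 21895 in KO, over 46.8 and 44.0 Mb.

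**Figure D1:**
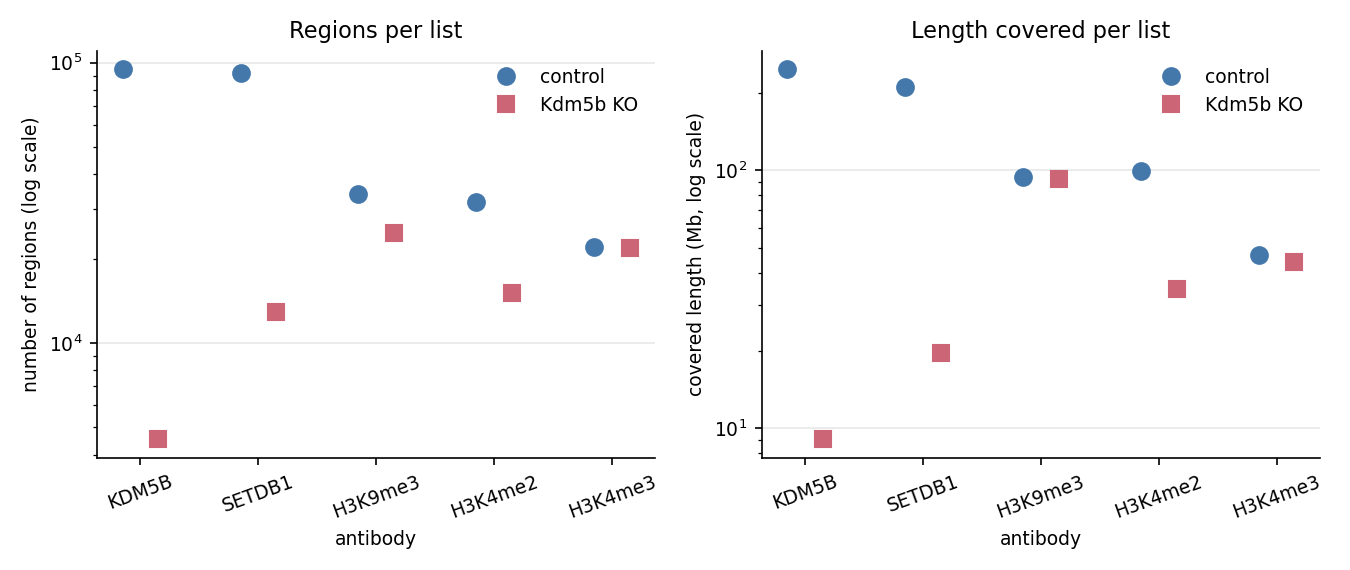
Number of regions (left) and covered length in Mb (right), both on log scales, for the 5 antibodies in control (circles) and Kdm5b KO (squares), 1 pooled list per symbol. The KDM5B list holds 94785 regions in control and 4543 in KO, and the H3K4me3 lists hold 22040 and 21895.

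KDM5B regions were found at the ends of 14102 of 21887 genes in control and of 73 in KO, and 63 genes had one in both. The widest control regions lay near Atg7, an autophagy gene (chromosome 6, 114488771 to 114639079, 150309 bp), over Casz1 and Pex14 (chromosome 4, 148871990 to 148975540), over Rbm19 (chromosome 5, 120116392 to 120219431), across an end of Gas8 and mostly outside it (chromosome 8, 123536268 to 123624509) and over Ccdc85c and Ccnk (chromosome 12, 108197869 to 108282793). Among them the Gas8 region also had a KO KDM5B region. The genes with the widest control-only regions at a gene end were Casz1, a zinc finger transcription factor, Pex14, a peroxisomal membrane protein, Rbm19, Ccdc85c, Ccnk, the retinoid X receptor gene Rxra, the nuclear receptor corepressor gene Ncor2, Rflna, the calcium channel gene Cacna1h and the tryptase gene Tpsb2, under regions of 74048 to 103551 bp. The 10 genes with a KDM5B region in KO only included Nme9 (11519 bp), N6amt1 (6734 bp), Cstdc2 (2353 bp), Olfr196 (1872 bp), Sprr2a2 (1591 bp), Olfr1475 (1283 bp), Clec4b1 (1115 bp) and Ube2u (1076 bp).

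Of the control KDM5B regions, 3.61% (3.49 to 3.73) were found in KO, against 0.785% after circular shifts. Of the KO regions, 73.9% (72.6 to 75.2) were found in control, against 15.6% after shifts. The KO list comes from cells in which the antibody's target gene is deleted and serves as the background list of that antibody. When the control list was limited to its 4543 widest regions, the share of KO regions found in control came to 1.28% and that of control regions found in KO to 1.36%. The widest control regions were therefore mostly not at the KO positions.

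SETDB1 regions were found at the ends of 14029 genes in control and of 3352 in KO, with 3053 genes in both. After the region near Atg7 (chromosome 6, 114488880 to 114638383, 149504 bp), the widest control regions lay across an end of Gas8 (chromosome 8, 123536289 to 123624568), over Ncor2 and Rflna (chromosome 5, 124995810 to 125082342), over Zfpm1 (chromosome 8, 122273194 to 122340116) and over Chd5 and Kcnab2 (chromosome 4, 152337393 to 152403280). All 5 had a KO SETDB1 region somewhere along their length. The genes whose ends carried the widest regions in control only were Rflna (86533 bp), Zfp469 (66923 bp), the potassium channel gene Kcnab2 (65888 bp), Dohh with its neighbours Gm48552 and Smim24 (51222 bp), Hdgfl2 with the perilipin genes Plin4 and Plin5 (50483 bp) and Klhdc4 (49529 bp). The 10 widest at a gene end in KO only were narrower, from 2042 to 3167 bp. They lay at H2-Ab1, a class II histocompatibility gene (3167 bp), Kctd15 (2543 bp), Olfr585 (2494 bp), Bbx (2336 bp), Dek (2248 bp), the chromatin remodeller gene Chd7 (2147 bp), Mrpl22 (2142 bp), the cyclin gene Ccnb3 (2129 bp), Olfr39 (2059 bp) and the interferon regulatory factor gene Irf2 (2042 bp). Of the control SETDB1 regions 10.1% (9.91 to 10.3) were found in KO, and of the KO regions 72.2% (71.4 to 73.0) were found in control, against 1.92% and 13.3% after shifts. The share of KO regions found in control was far lower when the control list was cut to the length of the KO list.

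H3K9me3 was listed at the ends of 3128 genes in control and of 1781 in KO, and 1291 genes had it in both. The widest control regions lay over Kazn (chromosome 4, 142125694 to 142257642, 131949 bp), Ajap1 (chromosome 4, 153391110 to 153519331, 128222 bp), Igsf21 (chromosome 4, 140098609 to 140194005) and Ccdc60 (chromosome 5, 116153193 to 116245143), and between genes with Igsf21 as the nearest (chromosome 4, 140311997 to 140402654). In KO the region over Kazn was 350520 bp and that over Ajap1 321052 bp. Control regions already covered 94.9% of the KO region over Kazn, in 11 pieces, and 97.2% of that over Ajap1, in 7 pieces, so the wider KO regions there were mainly closed gaps. Regions of 100 kb or more numbered 2 in control and 29 in KO, and those of 20 kb or more 191 and 354. Of the length in the KO regions of 20 kb or more, 82.7% was covered by control regions.

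**Figure D2:**
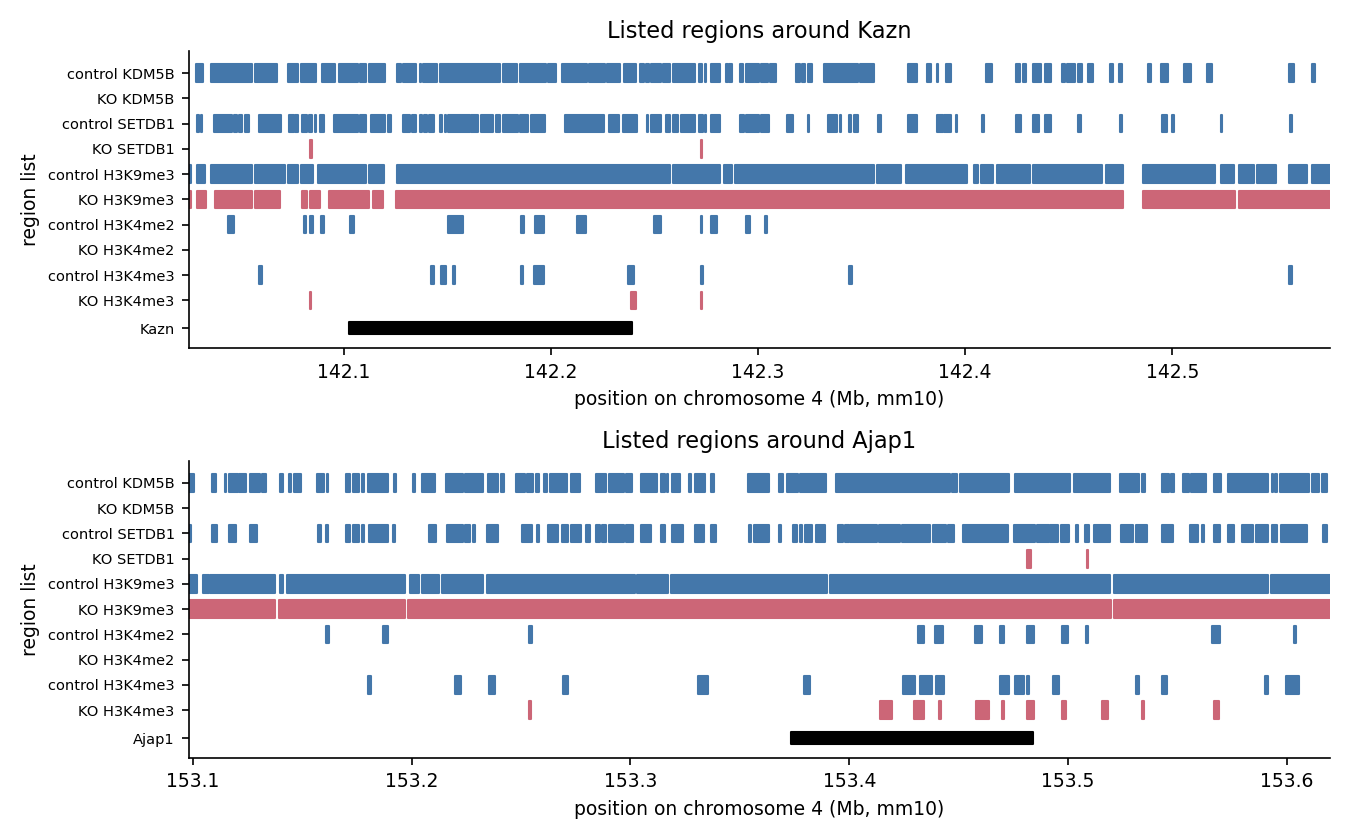
Listed regions of all 10 lists around Kazn and Ajap1 on chromosome 4 (position in Mb, mm10; blue control, red Kdm5b KO; black, the annotated gene), with 100 kb shown either side of the KO H3K9me3 region. H3K9me3 forms 1 region in KO where control has 11 pieces at Kazn and 7 at Ajap1, while KDM5B and SETDB1 regions are dense in control and few or absent in KO.

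The genes with the widest H3K9me3 regions in control only at a gene end were Mroh2a (37000 bp), Pld4 (21861 bp), the fibroblast growth factor receptor gene Fgfr3 (14020 bp), Slc29a4 (13979 bp), the ETS factor gene Spdef (13900 bp), Llgl2 and Myo15b (13301 bp), the Wnt pathway gene Axin2 (12872 bp), Pou6f1 (12751 bp) and Dnajb8 (12172 bp). Those listed in KO only were Pramel14 (23730 bp), Zfp987 (22842 bp), Ttc34 (14253 bp), Pramel6 (13646 bp), Foxk2 (11926 bp), Gm9789 (11733 bp), Pramel30 (11619 bp), the natural killer cell ligand gene Ulbp1 (11539 bp), Gm51591 (11075 bp) and Gm51592 (10917 bp). The region at Mroh2a overlapped a KO H3K9me3 region elsewhere along its length, so control only holds there for the gene ends alone. Pramel6, Pramel14 and Pramel30 belong to a multicopy family, where reads can be shared between near-identical copies. Of the control H3K9me3 regions 56.3% (55.8 to 56.8) were found in KO, and of the KO regions 69.9% (69.3 to 70.4) in control. The former was 37.1% when 50% of both regions had to overlap.

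H3K4me2 was listed at the ends of 12633 genes in control and of 9159 in KO, of which 8826 were shared. The genes with the widest regions in control only at a gene end were Tjp3, Tbxa2r and Gipc3 under a region of 48942 bp on chromosome 10, the retinoic acid receptor gene Rara (26866 bp), Crip1 and Gm30599 (26761 bp), Matk, Mrpl54 and Apba3 (24783 bp) and Fam83e (24406 bp). The region of 48942 bp overlapped a KO H3K4me2 region elsewhere along its length, so control only holds there for the gene ends alone. KO-only regions at gene ends were narrower and lay at Mcl1, an anti-apoptotic gene (6123 bp), Scpep1 (5367 bp), the neural transcription factor gene Olig2 (5297 bp), the granzyme gene Gzmf (4693 bp), Pank3 (4598 bp), Tra2b (4590 bp), Zfp950 (3652 bp), Insl6 (3590 bp), the hyaluronan synthase gene Has2 (3561 bp) and Msl1 (3544 bp). Of the control H3K4me2 regions 39.4% (38.9 to 39.9) were found in KO, and of the KO regions 84.8% (84.3 to 85.4) were found in control. The latter share was much lower when the control list was cut to the length of the KO list. Of the control regions found in KO 44.4% were centred at a gene end, and of the control-only regions 14.1%.

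H3K4me3 was listed at the ends of 12516 genes in control and of 12891 in KO, and 12100 genes had it in both. Another 416 genes had it in control only and 791 in KO only. In control only it lay at Acot8 and Spata25 (8074 bp), the receptor gene Ager (6642 bp), Tepp (6573 bp), Nfkb2, a subunit of NF-kappaB (6520 bp), Ccdc114 (6489 bp), Lims2 and Myo7b (6405 bp), Gm52236 (5995 bp) and Pdia2 (5344 bp). In KO only it lay at 4930404N11Rik (15061 bp), Baiap2 (13578 bp), Tjp3 (10233 bp), the AP-2 transcription factor genes Tfap2a (10061 bp) and Tfap2c (6045 bp), the adenylate kinase gene Ak1 (9226 bp), the nuclear receptor gene Nr5a1 (8711 bp), Rhbdf2 (8382 bp), the homeobox gene Evx2 (7118 bp) and Tnp2, a sperm nuclear protein gene (6099 bp). Tjp3 thus had H3K4me2 in control only and H3K4me3 in KO only at a gene end. Of the control H3K4me3 regions 77.5% (77.0 to 78.1) were found in KO, and of the KO regions 78.1% (77.5 to 78.6) in control, against 3.77% and 3.79% after shifts.

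**Figure D3:**
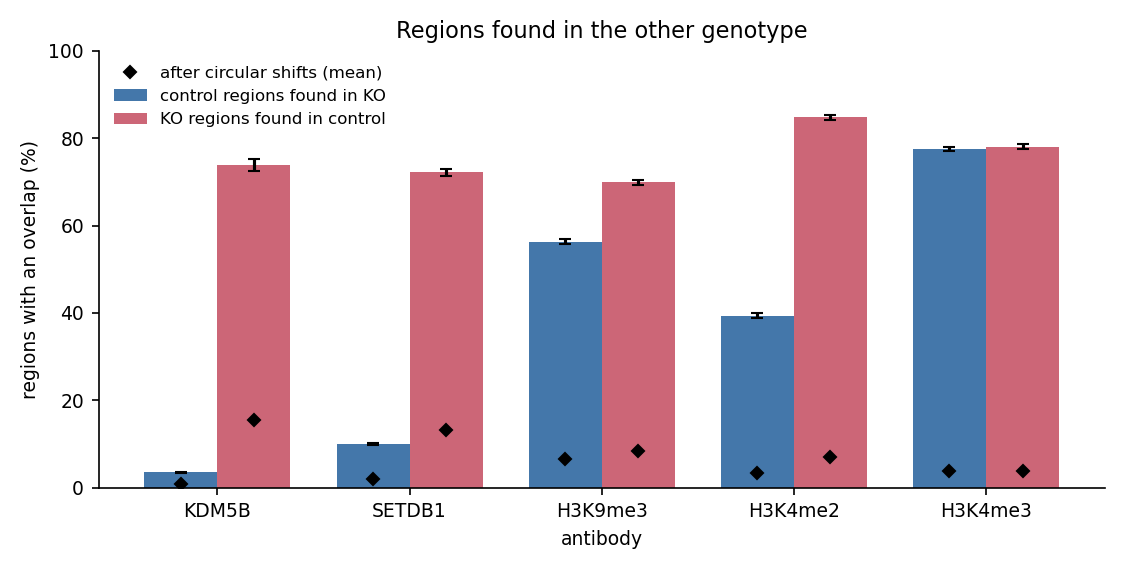
Percentage of control regions found in KO (blue) and of KO regions found in control (red) for each antibody, with 95% Wilson intervals, and the mean after 200 circular shifts (diamonds). Control regions found again range from 3.61% for KDM5B to 77.5% for H3K4me3, and each share lies above its shifted mean.

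Within control cells, KDM5B and SETDB1 lay at largely the same places. Of the control KDM5B regions 73.3% (73.0 to 73.6) overlapped a SETDB1 region, 4.31 times the mean of the shifted lists, and 81.6% of SETDB1 regions overlapped a KDM5B region. KDM5B regions overlapped H3K9me3 in 28.6%, H3K4me2 in 27.2% and H3K4me3 in 17.2% of cases, at 3.91, 3.65 and 4.02 times the shifted means. None of the 1000 shifts gave an overlap as high for any of these pairs, and the same held for the 6 pairs among the other antibodies. KDM5B, SETDB1 and H3K9me3 all overlapped in 24993 stretches covering 43.2 Mb. The widest of these lay across an end of Gas8 and mostly outside it (chromosome 8, 123536372 to 123624214), on chromosome X with Asmt as the nearest gene (170808669 to 170867497), at the start of chromosome 9 (3000043 to 3037995), over Hjurp and Mroh2a (chromosome 1, 88233219 to 88270218) and over Nphp4 (chromosome 4, 152543703 to 152577008). The first 3 of these had regions in all 10 lists, the KO KDM5B list included. Of the 24993 stretches, 61.6% (61.0 to 62.2) overlapped a KO H3K9me3 region.

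In KO cells 74.6% (73.4 to 75.9) of the 4543 regions in the KDM5B background list overlapped SETDB1, 42.8 times the shifted mean, and 64.3% overlapped H3K9me3. The shifted mean for KDM5B with SETDB1 was 1.75% in KO and 17.0% in control. It depends on list length, so the ratios of the genotypes are not comparable. KDM5B regions with both SETDB1 and H3K9me3 made up 24.3% in control and 59.7% in KO. SETDB1 regions overlapped H3K9me3 in 28.2% of control and 48.5% of KO cases, and H3K4me3 in 18.2% and 54.8%. H3K4me2 regions overlapped H3K4me3 in 53.5% of control and 83.4% of KO cases. When the centre of a region had to lie inside the other region, the ratio was 7.02 for control KDM5B with SETDB1 and 89.0 for KO KDM5B with SETDB1.

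**Figure D4:**
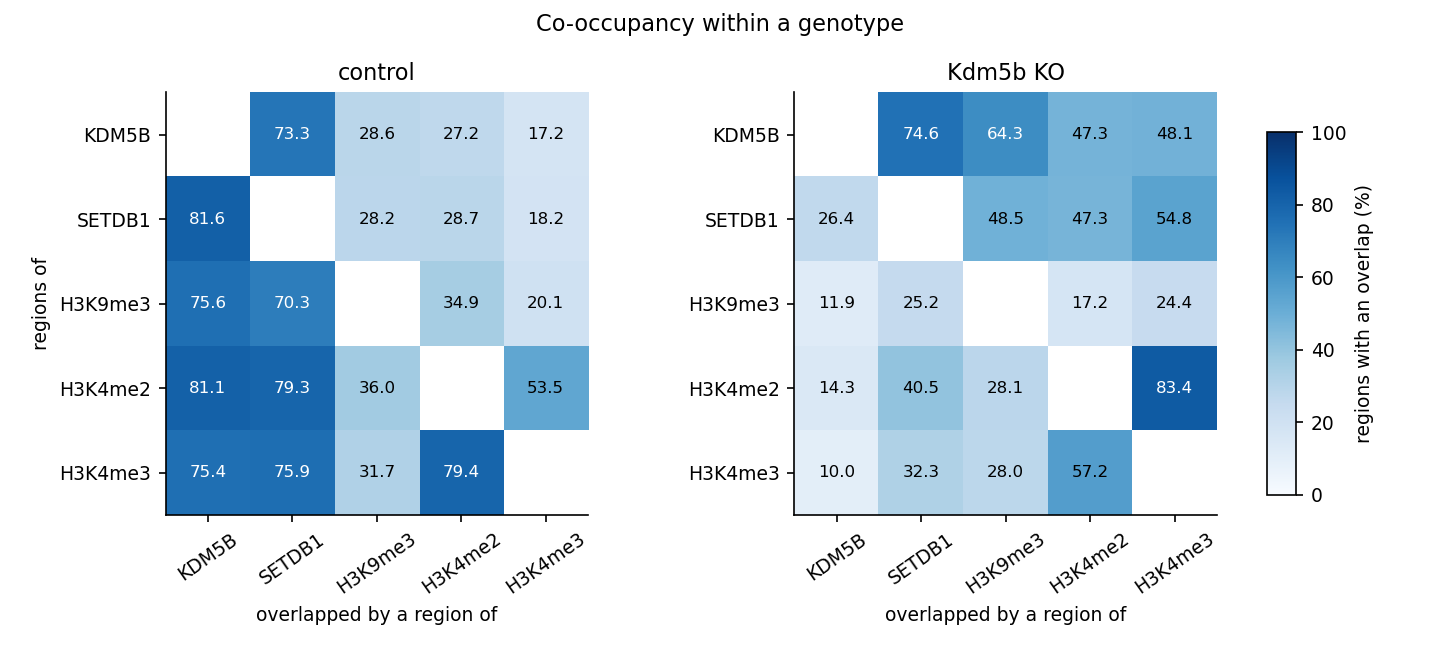
Percentage of the regions of the row antibody that overlap a region of the column antibody, in control (left) and Kdm5b KO (right), with the shade giving the same percentage. KDM5B with SETDB1 stands at 73.3% in control and 74.6% in KO, while SETDB1 with KDM5B stands at 81.6% and 26.4%.

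The next comparison asked whether the other regions were found again in KO less often where KDM5B had been. SETDB1 regions with a control KDM5B region were found again in 12.0% of cases and those without in 1.96%, a difference of 10.0 points (9.56 to 10.4) at matched width. The share without was near the 1.92% of all control SETDB1 regions after circular shifts. The shares were 58.8% and 50.9% for H3K9me3, a difference of 7.91 points (6.74 to 9.10), and 40.5% and 32.3% for H3K4me2, a difference of 8.23 points (6.77 to 9.63). H3K4me3 went the other way, with 76.8% and 80.5% found again, a difference of -3.71 points (-4.83 to -2.50). In the widest of the 5 width classes of H3K9me3 the order also turned, with 77.2% found again with KDM5B and 83.8% without, and the widest 50% of the lists gave -12.4 points. Counting as KDM5B regions only those absent from KO turned the sign for SETDB1 (-11.0 points), H3K9me3 (-6.78) and H3K4me2 (-7.37), because it places regions at the positions of the KO KDM5B list among those without. Leaving regions at KO KDM5B out of both classes, an alternative chosen after the data were seen, gave 7.01, 2.66 and 4.46 points for these, and -5.41 for H3K4me3. In the narrowest width class of H3K4me3 the order turned, with 61.0% (59.2 to 62.8) found again with KDM5B and 56.0% (53.6 to 58.4) without, and without width classes H3K4me3 gave 1.61 points.

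KDM5B regions were centred at gene ends in 10.1% (9.87 to 10.2) of control cases and 0.352% (0.217 to 0.571) of KO cases, against 2.89% of random positions. SETDB1 regions were at gene ends in 11.0% in control and 19.7% in KO, and H3K4me2 regions in 26.0% and 42.6%. H3K4me3 regions were there in 41.0% and 44.2%, and H3K9me3 regions in 4.96% and 3.67%. Of the control H3K4me3 regions also found in KO 51.1% (50.4 to 51.8) lay at a gene end, which counts either end of a gene. Control-only H3K4me3 regions lay there in 6.21% of cases and KO-only ones in 14.3%. Between genes lay 74.4% of the KO KDM5B regions and 69.2% of the KO H3K9me3 regions, against 59.9% of random positions.

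Germline genes such as Dazl and Ddx4, silent in most somatic cells, had H3K4me3 at more members in KO than in control. Of 23 genes, 2 had an H3K4me3 region in control and 8 in KO, with 7 in KO only and Hormad1 in control only. The KO-only genes included Ddx4 (646 bp), Mael (617 bp) and Sycp1 (595 bp), and Dazl kept its region (1387 and 1058 bp). The net count lay at percentile 99.7 of random lists matched on control H3K4me3. All of these regions were narrow, and the widest 50% of the lists held none of them in either genotype. H3K9me3 was found at 8 germline genes in control and 11 in KO, with Ddx4, Slc25a31 and Sycp3 among the 4 in KO only and Dazl and Mael in both. In the widest 50% of the lists these were 2 and 1. H3K4me2 went the other way, at 4 germline genes in control and 1 in KO, with Dazl, Mael (749 bp) and Sycp2 in control only and Sycp1 in both. KDM5B was at 20 of the 23 in control and at none in KO, against 64.4% and 0.334% of all genes.

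The 23 genes of the imprinted list include Nckap1, taken for H19 through a synonym, so its counts and percentiles carry a gene outside the plan. Imprinted genes had H3K4me3 at 14 of 23 in control and 17 in KO, the added ones being Cdkn1c (2350 bp), Kcnq1 (683 bp) and Ndn (1077 bp), with 11 in each genotype in the widest 50% of the lists. That net count lay at percentile 98.8 of matched random lists. Their H3K9me3 count was 14 in control and 11 in KO, with Dlk1, Gnas, Grb10 and Igf2 in control only and Cdkn1c and Igf2r in both. In the widest 50% of the lists it was 6 and 8. Among 20 melanocyte lineage genes, 6 had H3K4me3 in control and 10 in KO. The 4 in KO only were Gpr143 (587 bp), Rab38 (543 bp), the receptor tyrosine kinase gene Kit (1208 bp) and Tfap2a (10061 bp), while Gpnmb and Mc1r had it in both. The net count lay at percentile 98.7 of matched random lists, but in the widest 50% of the lists the count was 5 in control and 4 in KO. All 18 neural crest and dedifferentiated melanoma genes, Axl and Egfr among them, had H3K4me3 in both genotypes.

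Nucleic acid sensing genes had H3K4me2 at fewer members in KO than in control. H3K4me3 was at 17 of 24 in both genotypes, including Cgas, the cytosolic DNA sensor, and Adar, but in the widest 50% of the lists at 12 in control and 7 in KO. H3K4me2 was at 16 in control and 5 in KO, with the RNA sensor genes Ifih1 (1150 bp in control) and Dhx58 (4013 bp), and Ikbke (5289 bp) and Irf3 (10528 bp), in control only. That net count lay at percentile 0.100 of matched random lists. Of 25 interferon-stimulated genes, 15 had H3K4me2 in control and 7 in KO. H3K4me3 was at 19 and 16 of them, lacking in KO at Gbp2 (573 bp in control), Ifit1 (848 bp) and Isg15 (2792 bp) and present in both at Bst2 and Cmpk2, and in the widest 50% of the lists at 8 and 5. The control counts of KDM5B were 19 of 24 sensing genes and 14 of 25 interferon-stimulated genes, none of them in KO. Over all genes KDM5B was at 64.4% in control and 0.334% in KO, so having none in KO does not set these lists apart. Ifih1 and some others stand in both lists.

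Antigen presentation genes had KDM5B at 18 of 20 in control, including Cd74 (15603 bp), the class II transactivator gene Ciita (5471 bp) and Cd274 (1190 bp), the gene of PD-L1, and at none in KO. H3K4me3 was at 17 of them in both genotypes, B2m and Calr included. H3K4me2 was at 15 in control and 10 in KO, with Calr, Cd274, Nlrc5 and Psmb10 among those in control only. H3K9me3 was at none in control and at Tapbp (1472 bp) in KO, but over gene bodies at 2 in control and 1 in KO. SETDB1 was at 15 in control and 2 in KO. Over all genes KDM5B was at 64.4% in control and 0.334% in KO, so having none in KO does not set this list apart. H3K4me2 was at 57.7% and 41.8% of all genes, and SETDB1 at 64.1% and 15.3%. Among matched random lists the net count lay at percentile 21.3 for H3K4me2, 18.975 for SETDB1 and 4.21 for KDM5B. The lower H3K4me2 and SETDB1 counts in KO were thus not particular to antigen presentation genes.

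Clustered protocadherins, neuronal adhesion genes in 3 neighbouring arrays, had KDM5B at 53 of 57 in control and none in KO. Their SETDB1 count was 52 in control and 1 in KO (Pcdha9), and their H3K4me2 count 44 and 2, with Pcdhac2 and Pcdhgc3 in both. H3K9me3 was at 41 in control and 25 in KO, lacking in KO at Pcdha11, Pcdha8, Pcdha9 and Pcdhac1 among others. Genes of an array can share an annotated end, so these are not independent cases, and over gene bodies the counts were 57 and 9 for SETDB1, 44 and 35 for H3K9me3 and 51 and 33 for H3K4me2. Hox genes had SETDB1 at all 39 in control and 9 in KO, and H3K9me3 at 21 in control and 5 in KO. Hoxa2 and Hoxa3 had H3K9me3 in control only, Hoxa11 and Hoxa13 in KO only, and Hoxa7 and Hoxb13 in both. Their H3K4me3 count was 33 in each genotype.

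Zinc finger proteins named Zfp had KDM5B less often than genes in general, at 190 of 367 (51.8%) in control against 64.4% of all genes. H3K9me3 was at 53 of them in control and 57 in KO, 37 of these shared, while over all genes the counts were 3128 and 1781. Zfp1 (2724 bp), Zfp110 (6482 bp) and Zfp160 (1544 bp) had it in KO only and Zfp213 (625 bp) in control only. At Zfp12 the region was 5489 bp in control and 17342 bp in KO, and at Zfp146 3608 and 15287 bp. With windows of 2.5 kb the counts were 80 and 71, and over gene bodies 120 and 97, so the order of the genotypes depended on the window. Many Zfp genes are close paralogues in clusters.

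Of the genes that make the marks, 14 of 22 in the H3K9 methylation and retroelement silencing list and 14 of 18 H3K4 methylation writers and erasers had KDM5B in control, and none did in KO. H3K4me3 was at 19 and 16 of them in both genotypes. Over all genes KDM5B was at 64.4% in control and 0.334% in KO, so these KDM5B counts do not set the silencing genes apart. Daxx (7029 bp), Dnmt1 (9731 bp), Dnmt3a (2514 bp) and Cbx3 (787 bp) had KDM5B in control only. H3K4me2 at the silencing genes was at 13 in control and 14 in KO, the added one being Ehmt1 (2865 bp). At the writers and erasers it was at 15 and 13, lacking in KO at Kdm5a (2257 bp in control) and Rbbp5 (1414 bp). Both orders depended on the choices, since windows of 250 bp gave 13 and 12 silencing genes and the widest 50% of the lists 9 and 12 writers and erasers. Ribosomal protein genes had H3K4me3 at 77 of 80 in control and 76 in KO, Rpl17 being the difference, and H3K4me2 at 65 and 37. Olfactory receptors, silent outside the nose, had H3K4me3 at 1 of 1106 in control and 3 in KO, and KDM5B at 109 and 2. Lymphocyte and myeloid markers had H3K4me3 at 3 of 17 in both genotypes, Cd4 and Cd68 among them. The counts were 3 in control and 1 in KO in the widest 50% of the lists, and 1 and 2 over gene bodies. Keratinocyte, fibroblast and endothelial markers had it at 6 of 16 in control and 7 in KO, where Cdh5 (1387 bp) was added, and at 4 and 3 in the widest 50% of the lists.

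**Figure D5:**
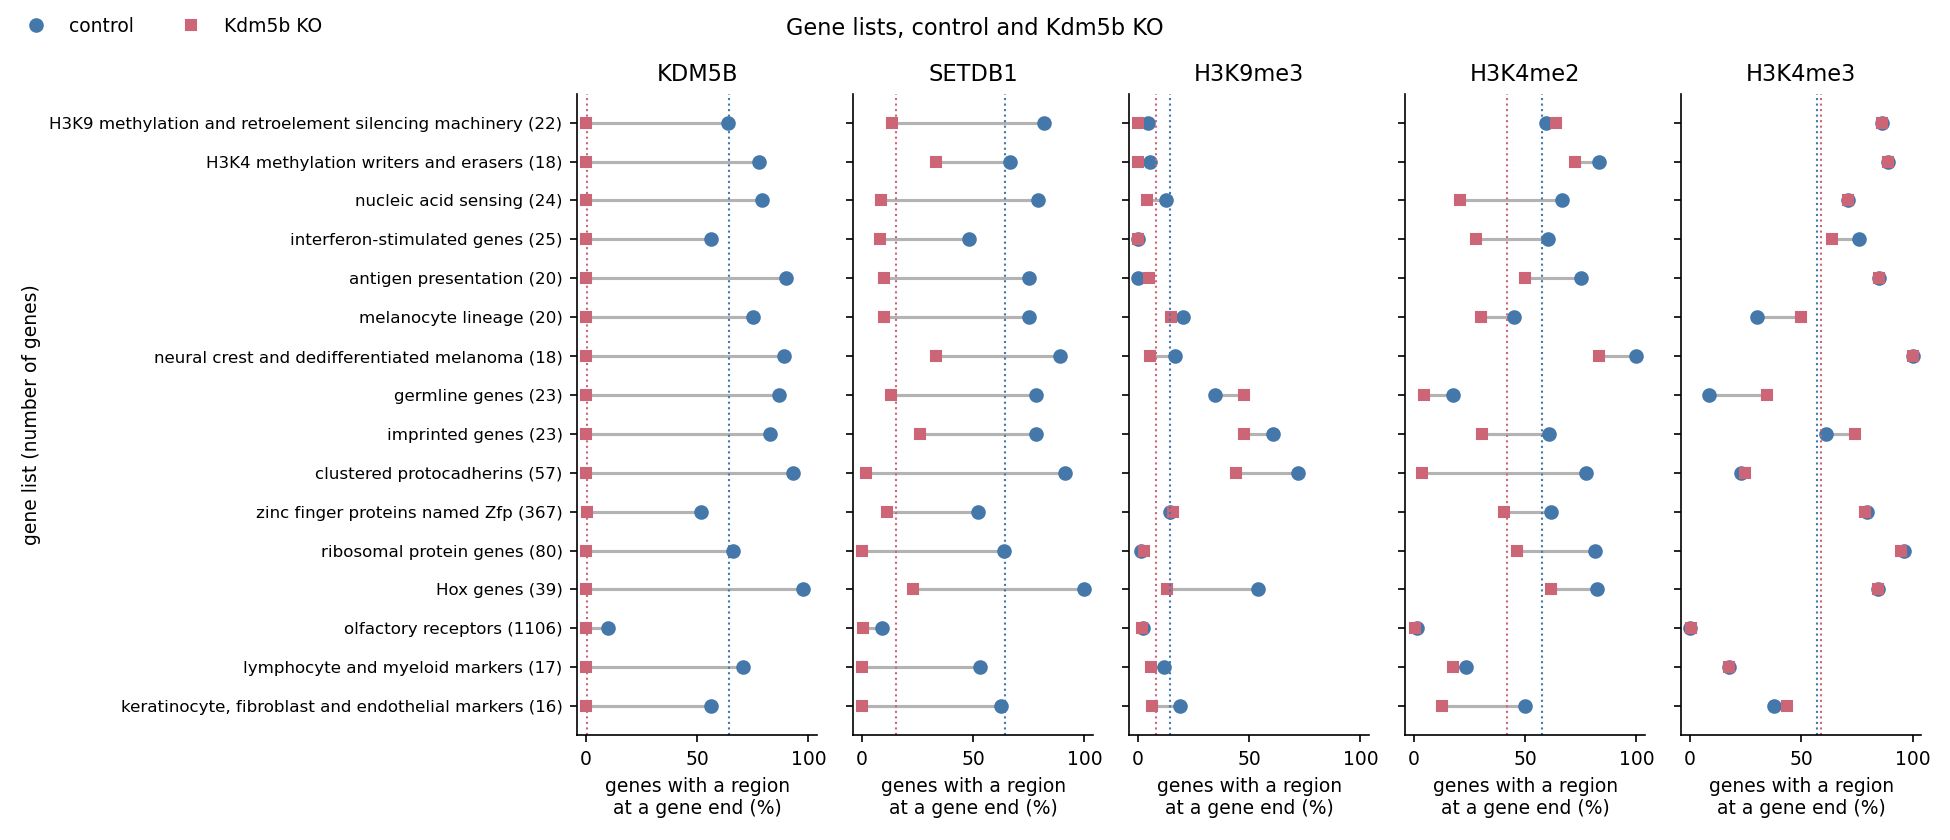
Percentage of the genes of each list with a region at a gene end, for each antibody, in control (circles) and Kdm5b KO (squares), with dotted lines at the percentage over all 21887 genes. KDM5B is at or near 0 in KO for all of the lists shown, while H3K4me3 moves most for germline genes, from 8.70% to 34.8%.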

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

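Alternatives chosen after the data were seen were autosomes only for co-occupancy and for regions found again with and without KDM5B, KO KDM5B regions left out of both classes, gene bodies, and gene lists and H3K4me3 differences without KO KDM5B regions; the others were planned. No paired analysis was possible because each deposited list pools its replicates, and for the same reason leaving out a replicate was not possible. Repeat content was not run, as no genome sequence was at hand. Restricting KDM5B to the combined list is void by construction, since that list is the merge of both. Depth is unknown, so the lists limit all counts to what passed an unknown threshold.

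Control regions found in KO stayed in the order KDM5B, SETDB1, H3K4me2, H3K9me3, H3K4me3 under each alternative. A reciprocal overlap of 50% gave 3.09% for KDM5B, 7.08% for SETDB1, 30.0% for H3K4me2, 37.1% for H3K9me3 and 66.4% for H3K4me3, lower by construction. The widest 50% of each list gave 3.20, 7.76, 33.0 and 68.7% for KDM5B, SETDB1, H3K4me2 and H3K4me3. Cutting the longer list gave 1.36, 10.7, 44.3 and 60.2% for KDM5B, SETDB1, H3K4me2 and H3K9me3. Autosomes gave 3.36% for KDM5B and 9.68% for SETDB1. For SETDB1, merging within 1 kb gave 10.4% and leaving out KO KDM5B regions 7.42%. Except for the reciprocal overlap, the cause was not tested. Of 27 values for KO regions found in control, 16 moved, and 1.28% for KDM5B with equal list lengths was the lowest. With equal list lengths the KO shares for SETDB1 and H3K4me2 also fell, to near the 10.7 and 44.3% given for control regions.

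Each co-occupancy ratio stayed above 1. For control KDM5B with SETDB1 it was 7.02 with the centre inside, 4.89 in the widest 50%, 4.34 with random placement, 4.25 on autosomes and 4.37 without KO KDM5B regions. With H3K9me3 it was 6.03 with the centre inside, 3.82 on autosomes and 3.86 without KO KDM5B regions, and with H3K4me2 5.18 with the centre inside and 3.61 on autosomes. With H3K4me3 it was 6.56 with the centre inside, 3.92 in the widest 50%, 3.96 on autosomes and 3.93 without KO KDM5B regions. For KO KDM5B with SETDB1 it was 89.0 with the centre inside, 53.4 in the widest 50% and 41.7 on autosomes. The cause was not tested. Among the other pairs 58 values moved and 14 did not.

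For regions found again with minus without KDM5B, counting only KDM5B regions absent from KO gave -11.0 points for SETDB1, -6.78 for H3K9me3, -7.37 for H3K4me2 and -5.75 for H3K4me3. It does so by construction, since regions at the positions of the KO KDM5B list join those without. Leaving them out of both classes gave 7.01, 2.66, 4.46 and -5.41. A reciprocal overlap of 50% gave 7.45, 12.8, 5.07 and -6.70, and the widest 50% gave 6.88, -12.4, 4.52 and -2.77, where H3K9me3 reversed. Without width classes H3K9me3 gave 14.2 and H3K4me3 reversed to 1.61, and autosomes gave 9.54 for SETDB1. Apart from the first alternative, the cause was not tested.

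Among gene lists, KO minus control counts stayed alike in 305 cases, moved in 91 and reversed in 12, and the cause was not tested. The widest 50% reversed writers and erasers for H3K4me2 (3), melanocyte genes for H3K4me3 (-1), germline genes for H3K9me3 (-1), imprinted genes for H3K9me3 (2), olfactory receptors for H3K9me3 (3) and keratinocyte, fibroblast and endothelial markers for H3K4me3 (-1). Windows of 2.5 kb reversed Zfp genes for H3K9me3 (-9) and H3K4me3 (4), windows of 250 bp silencing genes for H3K4me2 (-1), and gene bodies antigen presentation for H3K9me3 (-1), protocadherins for H3K4me3 (-3) and Zfp genes for H3K9me3 (-23). All 20 alternative values for location moved. The H3K4me3 difference at control KDM5B was 18.3 points without KO KDM5B regions.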

Other observations

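Tests chosen only after the result was seen were those of equal antibody background, of lower library sensitivity, of SETDB1 loss mainly at KDM5B, of gene density, of the shared chromosome factor and of the calling threshold for H3K4me3; those of any long list and of H3K4me2 sites were written before their values were seen, but after an exploratory table had shown the pattern. The H3K4me3 regions listed in 1 genotype only overlapped H3K9me3 more often than the shared ones, without matching on width. Their median width was 1343 bp in control and 1243 bp in KO, against 1920 and 1725 bp for the shared ones. Of the shared control regions 25.2% overlapped control H3K9me3, of the control-only regions 54.2% and of the KO-only regions 59.5%. Of the KO-only regions 55.6% overlapped KO H3K9me3, against 39.3% of the control-only ones, and KO H3K4me2 lay at 24.9% and 10.5%.

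Chromosome X held 1.53% of the KDM5B regions in control and 6.78% in KO, and 1.21% and 5.88% of the SETDB1 regions. The other lists differed less, with 2.39% and 3.63% for H3K9me3 and 2.98% and 3.49% for H3K4me3. Of the regions merged over all lists, 1301 (1.10%) were present in all 10, among them the wide ones at Gas8, at the start of chromosome 9 and at the far ends of chromosomes X and Y. Emid1 on chromosome 11 lay under a KO KDM5B region of 53330 bp, the widest there after those at Gas8 and on chromosome X.

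The control KDM5B and SETDB1 lists were long and largely coincided, and both were many times shorter in KO. Antibody background equal in both genotypes is argued against as the only source of the control KDM5B list. The widest control KDM5B regions were at gene ends more often than the KO ones by 11.1 percentage points. Such a background could still make up part of the control list, and a background of the control libraries alone stays open. A loss of SETDB1 mainly where KDM5B had been, the biological explanation tested, is not decided. At matched width SETDB1 regions with KDM5B were found again more often, by 10.0 points (9.56 to 10.4). With regions at KO KDM5B left out of both classes it was 7.01 (6.53 to 7.34), a rule that replaced earlier ones after the values were seen. But regions without KDM5B were found again in 1.96% of cases, near the 1.92% of control SETDB1 regions after shifts. They may be weak calls, and width does not match signal strength. The lists thus show only that absence from the KO list was not confined to SETDB1 regions with KDM5B. Such absence need not be a loss of SETDB1. A lower sensitivity of the KO libraries could shorten the SETDB1 list, but width decides little: the share found again was 1.84 times as high in the widest as in the narrowest of 5 width classes for SETDB1 (5.45, then 14.0, and 10.0% in the widest), and KDM5B cannot speak to it, as its gene is deleted in KO. A first rule, a ratio of at least 1.5, was met and was replaced after these shares were seen, and lower sensitivity cannot be told apart from a loss of SETDB1 at sites with and without KDM5B, since neither depth nor signal strength is given.

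KO over control numbers of regions differed between chromosomes in a like order for several antibodies. Across the 19 autosomes the SETDB1 ratio was lower where genes were denser, with a Spearman rho of -0.635 (adjusted permutation p 0.0103). The KDM5B ratio was likewise lower (-0.709, adjusted permutation p 0.00475), while rho for H3K9me3, H3K4me2 and H3K4me3 was -0.0298, -0.128 and 0.121. These p-values come from permuting chromosomes within a single pair of lists, so they measure no spread between replicates. Per Mb, SETDB1 regions ranged over autosomes from 24.7 to 59.4 in control and from 4.00 to 5.91 in KO. The SETDB1 ratio thus varied mainly with the control numbers. Without the 2 chromosomes farthest out, 7 and 11, rho was -0.696 for SETDB1 and -0.608 for KDM5B. Over 10 pairs of antibodies the median rho of the ratios was 0.558 (lowest 0.275, highest 0.893), and 0.729 with the trend removed (lowest 0.502, highest 0.849). A factor shared by the libraries of a genotype, such as copy number, could thus add to gene density. But the lists share regions, as with 73.3% of control KDM5B regions at SETDB1, so the pairs cannot tell such a factor from this sharing. Which factor it is stays open, since no input values were used here, and no biological explanation was tested.

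H3K4me3 regions listed in KO only lay at control KDM5B regions more often than control-only ones. At matched width the difference was 17.3 points (15.8 to 18.7), which restates the pattern, so that regions near the calling threshold cannot be told apart from other differences between the lists without signal strength. A mark left by any long list is argued against only for regions with control KDM5B or SETDB1 but not both. There the KO-only share was 10.6 points (7.99 to 13.4) higher at KDM5B without SETDB1 than at SETDB1 without KDM5B. The contrast rests on 216 and 107 KO-only regions. It does not cover the 4141 of 4804 KO-only regions that lay at both, and control SETDB1 regions gave a difference of 18.6 points. KO-only regions also lay at control H3K4me2 more often, by 6.51 points (4.54 to 8.47), near the bound of 5 set beforehand, so a gain of H3K4me3 at H3K4me2 sites where KDM5B was lost cannot be told apart from other differences between the libraries. As a hypothesis, some of these regions could reflect the missing demethylase, but with 1 pooled list per genotype a difference between the cell clones stays open. H3K4me2, from which KDM5B also removes methyl groups, went the other way, with 19291 regions in control only and 2280 in KO only.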
